A study of Drosophila melanogaster with 3 samples.

How the data were processed

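The samples were whole Drosophila melanogaster embryos of 8 to 16 h, cross-linked in 1.8% formaldehyde for 15 min, per the labels' protocols. Chromatin from 150 mg of material was prepared, and the antibody was incubated for 4 h. There was 1 input sample and 2 HP1 ChIP replicates. The labels do not say whether the replicates came from separate embryo collections.

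The authors deposited 1 list of peaks for the whole series. Per the file headers, it uses FlyBase release 5 and a caller named MACS. Per the submitters' processing notes, the tools were CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2. The parameters, the peak threshold, the treatment of reads that map to several places and whether the replicates were pooled before peak calling are not given in the sources used here. The deposited score of each peak has no stated definition or scale. It was used to rank and filter peaks and to compare regions within the list, in its own units, so a difference of scores has no known scale. Score and width had a rank correlation of 0.761 across peaks, which are not independent, so a high score goes with a wide peak. The read depth per sample is unknown, so no counting error was attached to any peak. How reads from repeated sequence were placed may matter most on the Het sequences, U and Uextra, where repeats are common, but its effect was not measured.

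Starts were read as counting from 0, because 1 start equals 0, and positions are printed counting from 1. The list gives no sequence lengths. The end of the last peak was used as the length of each sequence, which sets the centromeric end of 2L, 3L and X and the telomeric end of 2R, 3R and 4. A peak was assigned to a region by its midpoint. Density was peaks per Mb. The centromere lies at high coordinates on 2L, 3L and X and at low coordinates on 2R and 3R. U and Uextra were described apart and left out of all comparisons.

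Folds of density were tested by sliding all peaks together by 100000 random offsets, around the joined sequences for chromosome 4, the Het sequences and the range among chromosomes, and around each arm for its ends. In the test, 0.5 peaks were added to each count. P-values over single arms were adjusted over the 5 arms by the Benjamini-Hochberg method. All tests were two-sided. Two-sided values were taken as the doubled smaller tail, a choice made after p-values based on the absolute log2 fold had been seen. Those counted empty windows as extreme. The absolute version is kept as an alternative, under which no single arm passed, while the calls for the 5 arms together and for the Het sequences held. Scores and widths were compared by medians over 4 classes (chromosome 4, Het sequences, proximal 1 Mb, rest of the arms). Values were rotated along the order of peaks, using all 5355 rotations, and adjusted over the 6 pairs for each measure. Clustering was compared with 1000 uniform placements of the same peaks within each sequence. For the rest of the arms the placements stayed outside the proximal 1 Mb. The threshold was 0.05. Intervals are the 95% range of 10000 resamplings of 100 kb bins. They describe variation along the sequence and say nothing about variation between samples. Bins were drawn as if independent, but dense bins lie side by side, so the intervals are probably too narrow.

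The density and rotation tests were tested on 200 simulated lists per setting. With no difference, 3% of lists passed for chromosome 4, 6.5% for the proximal 1 Mb and 6.5% for the score. These lists held small clusters spread evenly, without the long dense stretches of the deposited list, so these rates may not hold for it. With a true fold of 10, all lists passed, and the median estimates were 9.85 for chromosome 4 and 10.03 for the proximal 1 Mb. For the score, a true difference of 2 gave a median estimate of 2.002, and all lists passed. The simulated scores had an SD of 1, whereas the deposited scores had quartiles of 13.47 and 34.59. This pass rate therefore does not carry over to a difference of 2 in deposited score units. The lists with a fold of 10 on chromosome 4 had no dense inner arm ends, unlike the deposited list. Their pass rate therefore does not carry over to the chromosome 4 test here. The Het, telomeric, range, width and single-arm tests were not simulated.

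The regions named follow a rule fixed before the data were examined: the 10 highest scores, the highest score of each sequence, and the 10 chains with most peaks on the large arms outside the proximal 1 Mb. A chain joins neighbours closer than 5 kb. The outermost telomeric peaks, the widest peaks and the 20 highest placed scores were added after seeing the data. Tests, classes and most alternatives were also fixed before. The alternatives were a higher score limit (20.96 or 34.59), merging of peaks within 1 kb, the share of bases covered, windows of other sizes, arms without their proximal 2 Mb, means of log2 values, other chain distances and removal of extreme widths. A merged peak took the highest score of its members and their whole span, gaps included. The gene table used here is of release 6 and the peaks are on release 5, so gene positions were not used. The position of peaks relative to genes and the gene lists were not analysed here. No comparison between replicates was made, since the list marks none. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.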

Results

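The deposited data map heterochromatin protein 1 (HP1) along the Drosophila melanogaster genome in embryos 8 to 16 h old. HP1 is a chromatin protein best known from heterochromatin, the compact, repeat-rich part of the genome around the centromeres and on most of chromosome 4. The series holds 3 samples of whole embryos of a strain labelled Y cn bw sp: 1 input DNA sample and 2 chromatin immunoprecipitation (ChIP) replicates made with a rabbit polyclonal antibody to HP1. The processed data used here are a single list of 15755 HP1 peaks on 14 sequences of FlyBase release 5. The list does not mark which replicate a peak came from, so no value below has an error between replicates, and the read depth of the samples is unknown. Intervals given below come from resampling 100 kb bins along the sequences and describe unevenness along the genome only. Neighbouring bins are not independent, so these intervals are probably too narrow and do not replace the permutation tests.

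The peaks had a median width of 503 bp (quartiles 329 and 756 bp, range 200 to 26384 bp) and covered 12550105 bp. Each peak carries the authors' score, whose definition is not given in the sources used here. It ran from 6.25 to 220.1 with a median of 20.96, and is used below only within this list, in its own units. Of the 15755 peaks, 2257 (14.3%) lay on the 5 large arms 2L, 2R, 3L, 3R and X, and 268 on chromosome 4. The separately assembled heterochromatin sequences, whose names end in Het, held 2831 peaks (18.0%). The remaining 10399 peaks (66.0%) lay on U and Uextra, which collect sequence without a chromosomal place and enter none of the comparisons below.

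The first comparison asks how HP1 peaks were shared among the 6 placed chromosome sequences. Chromosome 4 had the highest density, 198.2 peaks per Mb (interval 159 to 241.4). Among the large arms, 2R had 32.2 peaks per Mb, 3L 29.1 and 2L 21.1, while X had 9.83 (6.17 to 14.2) and 3R 5.63 (4.12 to 7.28). Peaks covered 19.6% of chromosome 4, 5.16% of 2R, 3.68% of 3L, 2.77% of 2L, 0.843% of X and 0.520% of 3R. The highest density was 35.2 times the lowest. In a two-sided circular-shift permutation test, which slides all peaks together along the joined sequences and so keeps their clustering, this range had p = 0.193. Ranges that wide therefore also arose when the clusters of peaks were placed without regard to chromosome boundaries. The p is a doubled tail and not the share of such ranges. As the range runs from 3R to chromosome 4, it does not test whether the large arms differ among themselves.

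**Figure D1:**
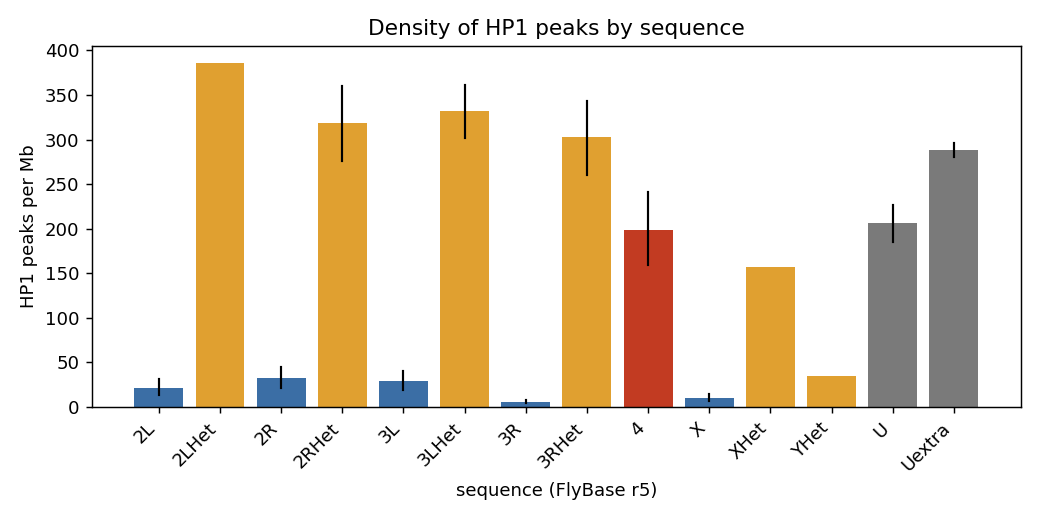
Bars give HP1 peaks per Mb for each of the 14 sequences, with the length taken up to the end of the last peak (blue, large arms; orange, Het sequences; red, chromosome 4; grey, U and Uextra). Lines are 95% intervals from resampled 100 kb bins, drawn for sequences of at least 1 Mb. 2LHet reached 385.8 peaks per Mb and 3R 5.63.

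Chromosome 4, a small chromosome known for its mixture of active genes and heterochromatin, carried 10.45 times the HP1 peak density of the 5 large arms together. It had 198.2 peaks per Mb against 19.0, with an interval of the fold from 7.85 to 13.9. Peaks lay along its whole length: each 100 kb held between 8 peaks, at 700 to 800 kb, and 37 peaks, at 1200 to 1300 kb. The share of bases covered was lowest at 700 to 800 kb, with 5.35%, and highest from 1300 kb to the end of the last peak, with 75.8%. The next highest was 33.5%, at 0 to 100 kb. Chromosome 4 also held 6 of the 20 highest scores on placed sequences, all of them at or beyond position 1293222. Against the whole arms the difference did not pass the two-sided permutation test (p = 0.0642), which also slides the dense inner ends of 2L, 2R and 3L into the place of chromosome 4. With the centromere-proximal 2 Mb taken off each arm, the arms had 6.975 peaks per Mb, and the fold was 28.4 (interval 21.6 to 37.2; permutation p = 0.00028). This removes, by construction, the dense inner ends that could take the place of chromosome 4. The smaller p therefore applies to the outer arms only and does not replace the test against the whole arms.

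The 6 Het sequences, assembled from pericentromeric and Y-linked heterochromatin, had 306.6 HP1 peaks per Mb, 16.2 times the density of the large arms (interval 13.3 to 20.0). This difference passed the two-sided circular-shift permutation test (p = 0.00018). Peaks covered 33.3% of the Het sequences and 2.49% of the arms. The sequences differed among themselves. 3LHet had 332.1 peaks per Mb and the highest share of bases under peaks, 42.8%, while 2LHet had 385.8 peaks per Mb and 33.95% covered. 2RHet had 318.8 and 3RHet 302.7 peaks per Mb. XHet was lower, with 156.9 peaks per Mb, and YHet had 12 peaks in 0.347 Mb, which is 34.6 per Mb.

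Towards the centromeres, HP1 peaks were concentrated at the inner ends of the arms. The centromere-proximal 1 Mb of the 5 arms together held 1099 peaks and the rest of the arms 1158. The density was 219.8 against 10.2 peaks per Mb, a fold of 21.6 (interval 15.9 to 28.8). In the two-sided permutation test with shifts within each arm, p was 2e-05, the smallest that 100000 shifts can give. The inner 1 Mb held 299 peaks on 2L, 315 on 2R, 379 on 3L and 87 on X, but 19 on 3R. These windows end with the arm sequence and leave out the separately assembled Het sequences. The low count on 3R thus does not cover 3RHet, which had 754 peaks at 302.7 per Mb. The extent also differed: the second Mb held 187 peaks on 2R and 182 on 3L, 17 on 2L, 7 on 3R and 5 on X. Beyond 3 Mb from the centromeric end, the 5 arms had low densities, from 4.94 peaks per Mb on 3R to 6.76 on 2L.

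Tested arm by arm with permutation within the arm, the proximal concentration passed on 3L (fold 26.6, p = 0.00014, adjusted over the 5 arms p = 0.0007) and on 2L (fold 35.3, p = 0.0122, adjusted p = 0.0306). It did not pass on 2R (fold 17.3, permutation p = 0.0409, adjusted p = 0.0511), X (fold 13.98, permutation p = 0.0359, adjusted p = 0.0511) or 3R (fold 3.70, permutation p = 0.106, adjusted p = 0.106). All 5 folds were above 1. Whether the arms differ from one another was not tested. The calls on single arms changed with the setting in both directions. Because the test slides peaks around their own arm, offsets that keep a dense stretch over the window count as extreme too. A stretch longer than the window can thus limit how small p gets. Failing on a single arm therefore does not show that proximal concentration is absent there. With windows of 0.5 Mb or 2 Mb, neither 2L (permutation, adjusted p = 0.0925 and 0.0823) nor 3L (permutation, adjusted p = 0.0925 and 0.0545) passed. With the two-sided permutation p taken from the absolute log2 fold instead of the doubled smaller tail, neither passed either (adjusted p = 0.129 for both). On X the fold was 1.65 in the inner 0.5 Mb (permutation, adjusted p = 0.274) and 7.32 in the inner 2 Mb (permutation, adjusted p = 0.13). By covered bases, 2R, 3R and X passed (permutation, adjusted p = 0.0282, 0.0282 and 0.032) while 3L did not (permutation, adjusted p = 0.0542), and with peaks within 1 kb merged 3R and X did (permutation, adjusted p = 0.0215 and 0.0317). Among peaks with a score of at least 20.96 neither 2L (fold 51.9, permutation, adjusted p = 0.0639) nor 3L (fold 28.0, permutation, adjusted p = 0.0789) passed, although the folds were not lower. With scores of at least 34.59, 2L (fold 67.2, permutation, adjusted p = 0.0423) and 2R (fold 27.2, permutation, adjusted p = 0.0413) passed, and 3L did not (fold 31.4, permutation, adjusted p = 0.078).

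**Figure D2:**
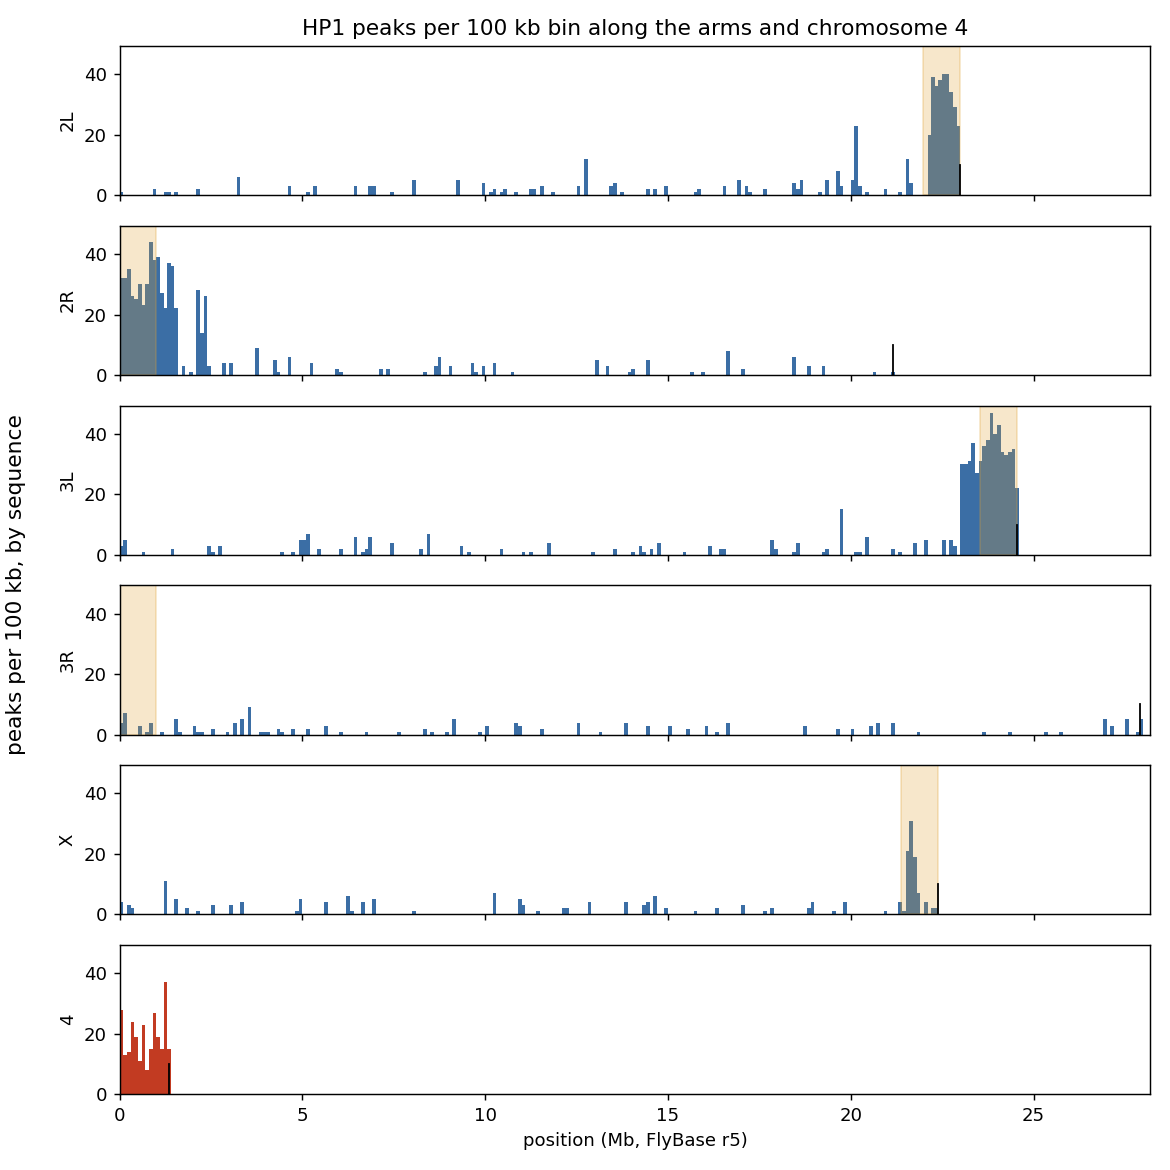
Each panel gives HP1 peaks per 100 kb bin against position in Mb for a large arm or chromosome 4. The orange band marks the centromere-proximal 1 Mb and the short black line the end of the last peak. Peaks crowd into the bands of 2L, 2R, 3L and X, extend past the band on 2R and 3L, and are spread over chromosome 4, while the band of 3R holds 19.

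At the telomeric ends, the outer 100 kb of the 5 arms held 15 HP1 peaks, a density 1.59 times that of the rest of the arms. This did not pass the two-sided permutation test (p = 0.408). Without 3R the fold was 0.975 and with a 200 kb window 1.055, while 5 other settings raised it to between 2.58 (scores of at least 20.96) and 4.40 (scores of at least 34.59), without passing (permutation p from 0.229 to 0.336). The rest of the arms includes the dense centromeric ends, which lower these folds. Beyond 3 Mb from the centromeric end the arms had 4.94 to 6.76 peaks per Mb, telomeric ends included. The outer 100 kb of the 5 arms had 30 per Mb, and this contrast was not tested. A fold near or below 1 here therefore does not show that a telomeric excess over the distal arms is absent. The outer 100 kb held 6 peaks on 3R (fold 11.05, permutation p = 0.0237, adjusted p = 0.119), 4 on X (fold 4.13, permutation p = 0.201, adjusted p = 0.503), 3 on 3L, 1 on 2L and 1 on 2R. Among peaks with a score of at least 20.96 the fold on 3R was 26.5 (permutation, adjusted p = 0.0374), and among those of at least 34.59 it was 57.5 (permutation, adjusted p = 0.0374). For X the latter gave 25.7 (permutation, adjusted p = 0.0448). The 3R fold was 3.92 with peaks within 1 kb merged (permutation, adjusted p = 0.583) and 5.504 in a 200 kb window (permutation, adjusted p = 0.301). The telomeric ends of 2R, 3R and 4 are taken here as the end of the last peak, because the list gives no sequence lengths, so a peak at that end is certain by construction.

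The outermost peaks, looked at after the counts were known, reached the first bases of the arms whose telomere is at the low end. On X the first peak ran from position 1 to 3857 (score 96.7), on 3L from 9 to 20106 (score 63.3) and on 2L from 30 to 5130 (score 47.4). The 3L peak, 20098 bp wide, was among the 5 widest on placed sequences. On X a second peak from 6162 to 9300 had the highest score of the chromosome, 145.9. The last 6 peaks of 3R, from 27899079 to 27904707, were 648 to 717 bp wide, and one of them, from 27901044 to 27901760, had the highest score of that arm, 95.5.

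**Figure D3:**
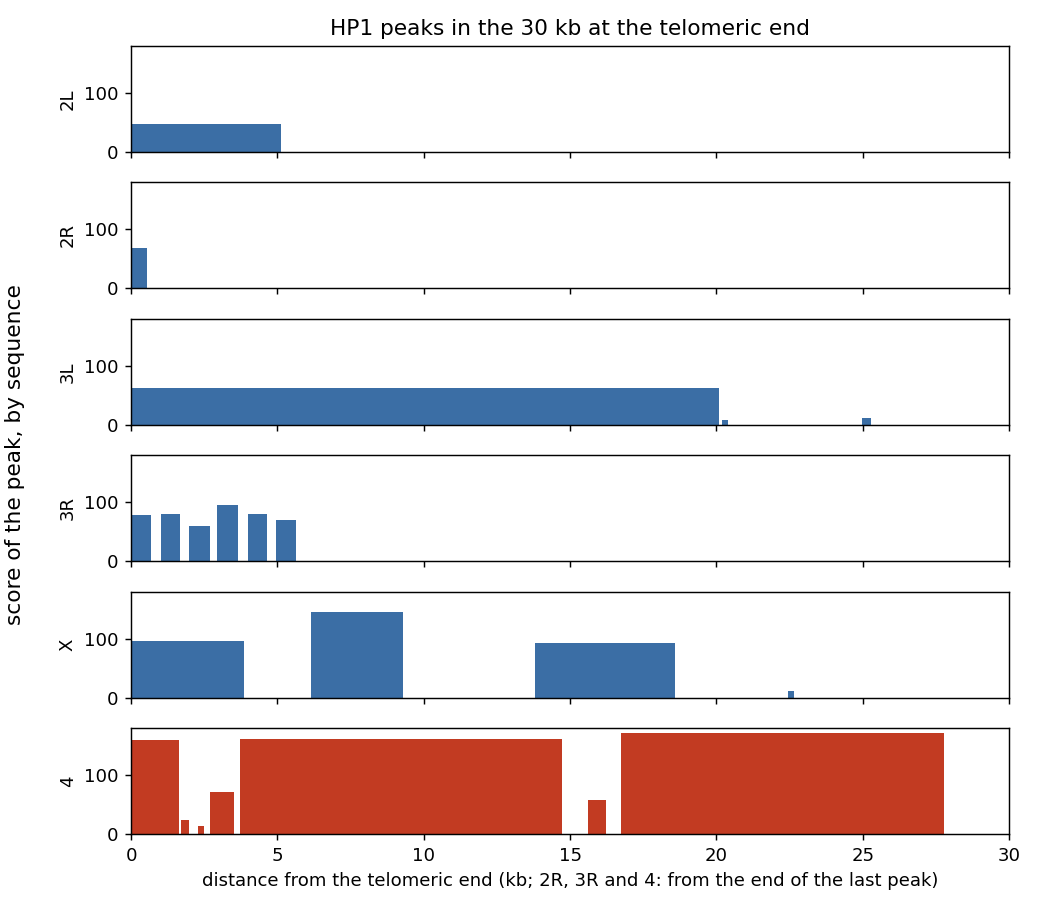
Boxes give the extent (horizontal, distance from the telomeric end in kb) and score (vertical) of each HP1 peak in the outer 30 kb of the 5 arms and chromosome 4. Ends of 2R, 3R and 4 are set by the last peak. 3R shows 6 separate peaks of 648 to 717 bp, and 3L a peak of 20098 bp followed by peaks of 208 and 293 bp.

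Where peaks lay was compared with how high they scored. Median scores were 19.8 on chromosome 4, 19.1 on the Het sequences, 22.4 in the proximal 1 Mb and 18.8 on the rest of the arms. The rest of the arms is not only distal sequence: 629 of its 1158 peaks lay beyond the proximal 3 Mb. The dense second Mb held 187 of its peaks on 2R and 182 on 3L. The difference of 3.56 between the proximal 1 Mb and the rest of the arms did not pass a two-sided permutation test that rotates the scores along the order of the peaks (p = 0.0941, adjusted over 6 comparisons p = 0.565). None of the other 5 comparisons of scores passed (adjusted permutation p from 0.747 to 0.785). Proximal minus rest was 13.04 with peaks within 1 kb merged (permutation, adjusted p = 0.122) and 0.24 as a difference of mean log2 scores (permutation, adjusted p = 0.0504), neither of which passed. A merged peak keeps the highest score of its members, so joining more peaks can by itself raise the score, and 13.04 is not comparable with 3.56.

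Median peak width was 742 bp (quartiles 356.5 and 1735 bp) in the proximal 1 Mb, 589.5 bp on the rest of the arms, 579 bp on the Het sequences and 575.5 bp on chromosome 4. The proximal excess of 152.5 bp over the rest of the arms did not pass the rotation permutation test (p = 0.0332, adjusted p = 0.0997), nor did the difference of the Het sequences from the proximal 1 Mb (-163 bp, permutation p = 0.0153, adjusted p = 0.0919). On a log2 scale the mean width in the proximal 1 Mb was higher by 0.28 than on the rest of the arms, which passed (permutation, adjusted p = 0.0325). That of the Het sequences minus the proximal 1 Mb was -0.32 and also passed (permutation, adjusted p = 0.0314). The medians differed by more, without passing, among peaks with a score of at least 20.96 (269 and -275 bp, permutation, adjusted p = 0.216 and 0.133) and with peaks merged (537 and -742 bp, permutation, adjusted p = 0.355 for both). Merged widths span several peaks and the gaps between them, so they are not comparable with the widths of single peaks. Peaks wider than 5 kb made up 5.64% of the proximal peaks, 3.63% on the rest of the arms, 2.76% on the Het sequences and 1.49% on chromosome 4.

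**Figure D4:**
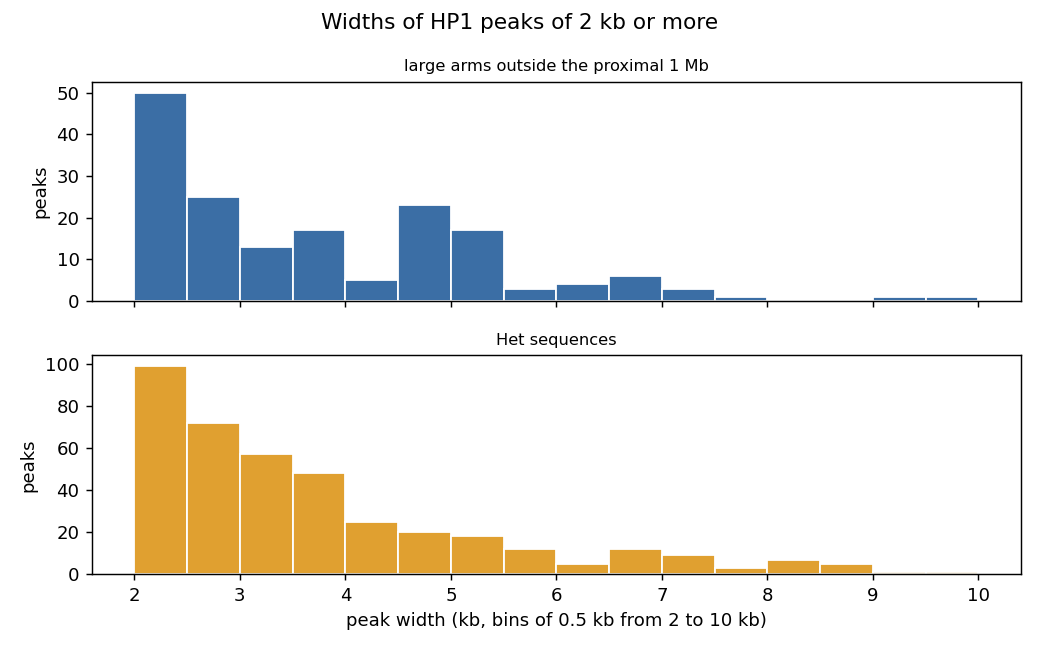
Number of HP1 peaks by width, in bins of 0.5 kb from 2 to 10 kb, on the large arms outside the proximal 1 Mb (top) and on the Het sequences (bottom), with separate vertical axes. The arms have 40 peaks between 4.5 and 5.5 kb, and the Het sequences 38 among a larger number of wide peaks.

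HP1 peaks lay in groups, most clearly on the arms. On the placed sequences, 97.0% of peaks had a neighbour closer than 5 kb, against a median of 67.0% in 1000 uniform placements within each sequence (permutation p = 0.002, the smallest these placements can give). The median gap between neighbours was 539.5 bp. On the dense sequences this measure was close to its upper limit: on the Het sequences the share was 98.8% against 97.2% at random, and on chromosome 4 98.1% against 89.9% (permutation p = 0.002 for each). Outside the proximal 1 Mb of the arms, where uniform placement would put 14.1% of peaks near another, 91.0% had such a neighbour (permutation p = 0.002). These 1158 peaks formed 310 chains, of which 104 were single peaks and 66 held at least 5. Only 629 of them lay beyond the proximal 3 Mb, and uniform placement ignores this unevenness, which alone raises the share with neighbours. Clustering was not rerun with peaks within 1 kb merged, so parts of a domain split by the caller count as neighbours.

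The 10 chains with the most peaks outside the proximal 1 Mb all lay on 2R and 3L, 5 on each. All but the chain on 2R from 2160869 to 2214921 lay in the second Mb from the centromeric end, next to the dense inner ends. Chains were built without the proximal peaks, so one at that limit may be cut short. The longest was on 3L from 23331565 to 23481266, with 54 peaks over 149702 bp and 73.6% of its bases covered. On 2R, 48 peaks lay from 1418416 to 1534148 (71.2% covered) and 32 from 1309019 to 1377912 (59.65%). A more distal chain on 2R, from 2160869 to 2214921, held 27 peaks and was less densely covered (46.5%). The other 6 chains held 16 to 25 peaks and spanned 32444 to 63650 bp, with 59.1% to 71.5% of bases covered.

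The 10 highest scores of the whole list lay on Uextra (5 peaks), chromosome 4 (3), U (1) and 2RHet (1). The highest, 220.1, belonged to a peak on chromosome 4 from 1313699 to 1317254. The other chromosome 4 peaks among them ran from 1293222 to 1298121 (score 196.9) and from 1324173 to 1335181 (score 172). The 2RHet peak, from 3181765 to 3195267, was 13503 bp wide with a score of 189.8. On Uextra the highest score was 212.8, from 747378 to 748739, and on U 177.6, from 7284476 to 7286597.

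On the arms the highest scores of 2L, 168.5 (22962587 to 22967979), and of 2R, 167.7 (719262 to 726491), lay in the proximal 1 Mb. That of 3L, 148.8, lay in the second Mb from the centromeric end (23288299 to 23309697), in a peak of 21399 bp. X and 3R differed, with their highest scores in the telomeric peaks given above. Among the Het sequences, 3LHet reached 153.5 (1404474 to 1412062), 3RHet 125.4 (1824802 to 1829201) and 2LHet 123.5 (190574 to 194313). YHet reached 89.3 (72036 to 75984) and XHet 69.5 (203100 to 203994). The widest peak on a placed sequence, 26384 bp, was on 2R from 742386 to 768769.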

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

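The tests in this part were all chosen after the counts on these sequences had been seen. U and Uextra, the sequences without a chromosomal place, are used by no comparison and yet held 10399 of the 15755 HP1 peaks. Uextra had 8329 peaks at 288.3 per Mb and U 2070 at 206 per Mb, against 306.6 per Mb on the Het sequences and 19.0 on the large arms. Peaks on them covered 16.0% of bases, against 33.3% on the Het sequences.

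If weak peaks near the caller's threshold made up this share, it should drop among high scores, but 66.17% of the peaks with a score of at least 34.59 lay there. If splitting of broad domains by gaps under 1 kb raised the share, merging should lower it, but after merging neighbours closer than 1 kb it was 77.83%. These values argue against both as the whole cause, for weakness as ranked by the undefined score and for gaps under 1 kb. Splitting by wider gaps or at scaffold ends was not tested. By bases under peaks, the share of U and Uextra was lower than by peaks, 6246900 of 12550105 bp. Reads shared between repeated copies, and repeated sequence present several times among the unplaced scaffolds, stay open and were not tested, as no genome sequence was used here. No biological explanation was tested.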

How the results depend on the processing

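Leaving out each arm or YHet and the absolute log2 fold p were tried only after the results were seen. For the main results, 61 alternative values kept direction and side of the threshold. The Het sequences (fold 12.41 to 43.95 over all alternatives) and the proximal 1 Mb over the arms (14.02 to 31.15) passed under each one run, and the telomeric 100 kb over the arms and the range among chromosomes under none. Chromosome 4 against the arms passed with peaks within 1 kb merged (fold 12.95, permutation p = 0.0392), with arms without their proximal 2 Mb (28.42, permutation p = 0.00028) and without arm 2R (12.3, permutation p = 0.0441). Its other alternatives gave permutation p from 0.0501 to 0.157. The mean log2 width of the proximal 1 Mb minus the rest of the arms was 0.284, past the threshold. The cause of these moves was not tested, except that taking off the proximal 2 Mb removes the dense stretches of the arms by construction.

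Small differences of score changed sign without passing in any setting. Het minus the rest of the arms was -0.01672 as a mean of log2 values and -0.35 without the narrowest and widest 5% of peaks, and with peaks merged chromosome 4 minus the rest was -2.52 and minus Het -3.56. On single telomeric ends, folds rest on a few peaks, and their direction was read with 0.5 peaks added. On 2L it turned with scores of at least 20.96 (0.9496) or 34.59 (1.623), merging (1.244), covered bases (1.849) and a 50 kb window (0.9477), and on 2R with scores of at least 34.59 (0.8733) and merging (0.9523). The cause was not tested.

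For single arms and the remaining pairs of classes, 60 values stayed, 10 lost and 10 gained a call. The lost ones were all proximal 2L or 3L. The gained ones were proximal 2R, 3R and X, telomeric 3R and X, and the log2 width of Het minus the proximal 1 Mb.

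Not run were the position relative to genes and the gene lists, another value per peak, the overlap of replicates and leaving out a replicate. No paired analysis was possible because the single list carries no replicate numbers. Depth is unknown, so absence of a peak cannot be told from low coverage.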

Other observations

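The regions, width range and tests in this part were all chosen after the data were seen. Away from the centromeres, HP1 peaks were sparse but locally dense. Of 1089 bins of 100 kb outside the proximal 2 Mb of the arms, 855 (78.5%) held no peak and 7 held 10 or more. The densest were 2 bins on 2R, with 28 peaks at 2.1 to 2.2 Mb and 26 at 2.3 to 2.4 Mb. Then came 23 peaks on 2L at 20.1 to 20.2 Mb (17% covered), 15 on 3L at 19.7 to 19.8 Mb (6.40% covered) and 14 on 2R at 2.2 to 2.3 Mb. From 2.1 to 2.4 Mb on 2R, 24.0% of bases were covered. The stretches on 2R and 2L are known for large piRNA clusters, loci rich in transposon remnants that give rise to Piwi-interacting RNAs. Beyond the proximal 3 Mb, the chain with most peaks was on X from 1252203 to 1261486, with 11 peaks and 66.1% of bases covered.

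YHet had the lowest HP1 peak density of the Het sequences, 34.6 per Mb against 317.2 on the others together (fold 0.109), and 2.42% of its bases were covered. It was picked for its low density, so the circular-shift permutation p of 0.00144 does not decide whether it stands apart. Its 12 peaks had a median score of 18.4, against 19.1 on the other Het sequences (difference -0.66, rotation permutation p = 0.884). The read depth on YHet is unknown.

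On the arms outside the proximal 1 Mb, 40 of the 87 peaks at least 3.5 kb wide were between 4.5 and 5.5 kb, against 38 of 171 on the Het sequences, 24 of 117 in the proximal 1 Mb, 2 of 10 on chromosome 4 and 20 of 81 on U and Uextra. A width favoured by the caller should act alike everywhere, and Fisher's exact p for the arms against Het was 0.000166. This range was picked from the widths themselves and neighbouring peaks are not independent, so the p does not decide, and such a width stays open. Single inserted elements of one length, such as transposons, could give peaks of one width in short chains: 18 of the 40 (45%) lay in chains spanning under 8 kb, against 11 of 47 other wide peaks (exact p = 0.0415). This cannot be told apart from distance to the centromere, because beyond 3 Mb 17 of 18 such peaks but also 10 of 12 other wide peaks lay in such chains, and nearer in 1 of 22 and 1 of 35 did. Of the 18, 6 were alone in their chain and 12 had a neighbour, in chains of 5992 to 6961 bp.

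The last 6 peaks of 3R were spaced evenly, by 965 to 1000 bp from start to start (mean 987.6, SD 14.7, 5 intervals). No other run of 5 intervals within 5% of each other and under 20 kb occurred in the list. When intervals were shuffled within each sequence, 19 of 1000 lists held such a run. The definition of a run was taken from these peaks, so this count does not decide whether the spacing arose by chance. Telomere-associated sequences of Drosophila are known to contain tandem repeats, and whether these peaks follow a repeat was not tested.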
